A study of Homo sapiens with 9 samples.

How the data were processed

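RNA from PANC-1, a human pancreatic adenocarcinoma cell line, was measured on 9 Affymetrix HG-U133 Plus 2.0 arrays. Cells were seeded in growth medium, changed the next day to a treatment medium with charcoal-filtered serum, and exposed for 72 hours to vehicle (DMSO) or to TVB-3166, named in the series title as a fatty acid synthase inhibitor, at 0.1 or 1.0 µM. Each condition has 3 arrays. The labels state triplicate treatments, and nothing further says that the replicates are separate cultures, so the p-values may measure technical spread rather than spread between cultures.

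The authors extracted total RNA, labelled it with biotin and deposited a hybridisation intensity per probe set on a linear scale. Per the submitters' processing notes these are MAS5 signals; the MAS5 version is not given in the sources used here. In the deposited values the mean of each array, trimmed by 2% at each end, is 500.1, which is a global scaling to 1 target. The labels also name Partek Genomics Suite and state no test, so no test of the authors was repeated.

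Some labels conflict. Samples were grouped by their titles. The treatment field of the 3 samples titled 1.0 µM gives 0.1 µM, while their title, source name and description give 1.0 µM. The description of 0.1 µM replicate 1 calls it DMSO. The DMSO concentration is given as both 0.05% and 0.5%. The design text also mentions 22Rv1 cells and a 48 hour treatment, which were not analysed here.

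Values were read as deposited and turned into log2(signal + 16) without a further normalization. The added 16 holds down noise at low signal and makes the printed folds smaller than the ratio of signals, most of all for dim genes. Of 54675 probe sets, 62 are array controls and were left out of the tests. Gene symbols came from the probe annotation supplied with the series and were updated by Entrez identifier to the human RefSeq annotation on assembly GRCh38.p14 (41043 of 41091 probe sets with 1 symbol). Probe sets with several symbols (1801) or none listed (11721) were not used for genes. Probe sets above the 40th percentile of mean level (a signal of about 38.95) were kept, 32768 in all. The probe set with the highest mean over all 9 arrays stood for each gene, which gave 13948 tested genes, 7020 of them with more than 1 probe set above the filter. Probe sets whose identifier ends in _s_at or _x_at can also bind related transcripts.

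The 3 groups were fitted in 1 linear model with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. The comparisons were 1.0 µM against DMSO, 0.1 µM against DMSO and 1.0 µM against 0.1 µM. All gene p-values are from limma's two-sided moderated test with 6 residual and 5.93 prior degrees of freedom, adjusted by Benjamini-Hochberg over all tested genes of the comparison. A gene was called at an adjusted p under 0.05. Errors on log2 changes are limma standard errors. Counts "adjusted over the list alone" adjust the same p-values over the tested members of a gene list only.

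For gene groups, 29 lists (691 genes, 558 tested) were written down from general knowledge. The 27 lists with at least 5 tested genes were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Each was tested again with an estimated correlation and with fry, using statmod 1.5.0. A list called by camera at the preset correlation counts as shifted; its call rests on that preset where the estimated correlation gives an adjusted p of 0.05 or more.

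Genes to be named followed a rule. For each dose against DMSO these were 8 genes of lipid synthesis and signalling (7 tested), the 8 largest rises and 8 largest falls with all 3 treated arrays on one side of the DMSO arrays, and up to 3 members with the smallest p from each called list until about 30 genes. For the doses against each other these were the 5 largest differences each way. Other members of the lists are named as examples, chosen after their values were seen.

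The grouping, tests, filters, gene lists, naming rule and 18 alternatives were fixed before the data were examined. The alternatives were other added constants (1 and 64), no filter or a filter at the 60th percentile, quantile or median normalization, the mean of a gene's probe sets or all probe sets, eBayes without trend or robust, only the 6 arrays compared, array weights, the replicate number as a block, each array left out in turn, a fold of at least 1.5 as well, the other set tests, and simulated controls for the overlap of doses.

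A split of the arrays by spike signal was seen only after the files were opened. Whether it marks a hybridisation batch is not known. The mean log2 signal of 9 hybridisation spike probe sets (BioB, BioC, BioDn and CreX) parts the arrays at 11.67 into a higher set of 4 (DMSO replicate 2, 0.1 µM replicates 1 and 3, 1.0 µM replicate 2) and a lower set of 5. The split crosses all groups but not evenly. Therefore 4 alternatives were added after the data were seen: the spike set as a block in the fit, the same after quantile normalization, and each spike set alone. Values within each spike set are printed beside the pooled values of the called lists, and for those genes named by the rule whose values in the sets differ by more than 1.5-fold. The lower set holds 2 DMSO, 1 0.1 µM and 2 1.0 µM arrays and the higher set 1, 2 and 1, so most comparisons within a set have a group of 1 array. By this split DMSO and 1.0 µM hold equal numbers of each set, so the block moves no mean change between them. The balance rests on placing DMSO replicate 3 (spike mean 11.41) in the lower set. Its 99th percentile signal (10947) also lies there. On the second principal component (16.6% of the variance) it lay at −4.90, near DMSO replicate 2 (−4.12) and away from replicate 1 (13.7). An imbalance between DMSO and 1.0 µM is thus not excluded.

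The median signal was similar across arrays, at 66.7 to 79.1. The 99th percentile was 9881 to 10947 in the lower and 12023 to 12494 in the higher spike set, so bright signals differed by spike set. With 3 arrays per group the number of arrays limits the precision. The code was tested on simulated data of 13948 genes, where changes of log2 0.5, 1 and 2 between 1.0 µM and DMSO were recovered in 32.8, 76.1 and 100% of genes, and 6 of 13748 unchanged genes were called. The vehicle arrays are shared by both doses, so fold changes at the doses are correlated even without an effect; 100 simulations of unchanged groups gave the size of this. The 3 vehicle arrays cannot be split into separate controls of at least 2 arrays each, and part of any excess overlap may come from the shared arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.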

Results

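The series asks what inhibition of fatty acid synthase does to the transcriptome of pancreatic tumour cells. PANC-1 cells were compared after 72 hours of DMSO, 0.1 µM or 1.0 µM TVB-3166, with 3 arrays per group. Values below are log2 changes of the signal ± limma standard error with n = 3 arrays per group unless stated. The first principal component held 40.5% of the variance and ordered the groups by dose (DMSO −32.5 to −31.9, 0.1 µM 5.91 to 12.9, 1.0 µM 22.7 to 24.5). Arrays of a group correlated across genes at 0.981 to 0.9899, where genes are not independent replicates. The log2 ratio of 3′ to 5′ GAPDH probe sets was −0.14 ± 0.05 in DMSO, −0.11 ± 0.01 at 0.1 µM and −0.18 ± 0.05 at 1.0 µM (mean ± SD, n = 3), and that of ACTB was 0.16 ± 0.03, 0.19 ± 0.06 and 0.17 ± 0.07. Spike controls averaged log2 11.54 ± 0.35, 11.80 ± 0.51 and 11.52 ± 0.49.

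At 1.0 µM against DMSO the largest rise on this scale was in IL32 (Entrez gene 9235, chromosome 16, 3065403 to 3069530), a proinflammatory cytokine, at 4.52 ± 0.16 (adjusted p = 1.69e-08). Its mean signal was 23.3 (SD 7.94) in DMSO, 464 (SD 19.8) at 0.1 µM and 877 (SD 85.7) at 1.0 µM, and the DMSO value lies below the filter level, so the fold is understated. SLCO4C1, an organic anion transporter, rose by 3.46 ± 0.27 (signal 84.9 to 1152) and S100P, a calcium-binding protein, by 2.83 ± 0.18 (235 to 1799). KLHDC7B rose by 3.28 ± 0.16, BEX2 by 2.77 ± 0.09, the Rab GTPase gene RAB39B by 2.75 ± 0.18, the actin-binding ABLIM3 by 2.75 ± 0.17 and the interferon-inducible GBP3 by 2.69 ± 0.16. Among the falls was ANGPTL4 (Entrez gene 51129, chromosome 19, 8364155 to 8374370), an inhibitor of lipoprotein lipase, at −2.50 ± 0.22 (adjusted p = 9.03e-06; signal 1684, SD 245, to 294, SD 101). ART5, an ADP-ribosyltransferase gene, fell by 2.47 ± 0.42. Other deep falls were CDH3 (P-cadherin) −2.39 ± 0.19, COL1A1 (Entrez gene 1277, a collagen chain) −2.32 ± 0.16, ADAMTS15 (a metalloproteinase) −2.29 ± 0.14, CDH10 −2.16 ± 0.23 and MXRA5 −2.10 ± 0.13. PROC, which encodes protein C, fell by 2.08 ± 0.27. At 1.0 µM the mean signals of ART5 (33.7) and PROC (13.1) lie below the filter level, so their falls are understated and the falls cannot be ranked. Between the lower and higher spike sets values differed for SLCO4C1 (3.88 and 2.62), S100P (2.63 and 3.24) and ART5 (−2.81 and −1.78). The 4 probe sets of COL1A1 spread from −2.47 to 0.09, so its fall depends on the probe set, as do the sizes of the rises of SLCO4C1 (1.10 to 3.46 over 2) and KLHDC7B (1.598 to 3.28 over 2).

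**Figure D1:**
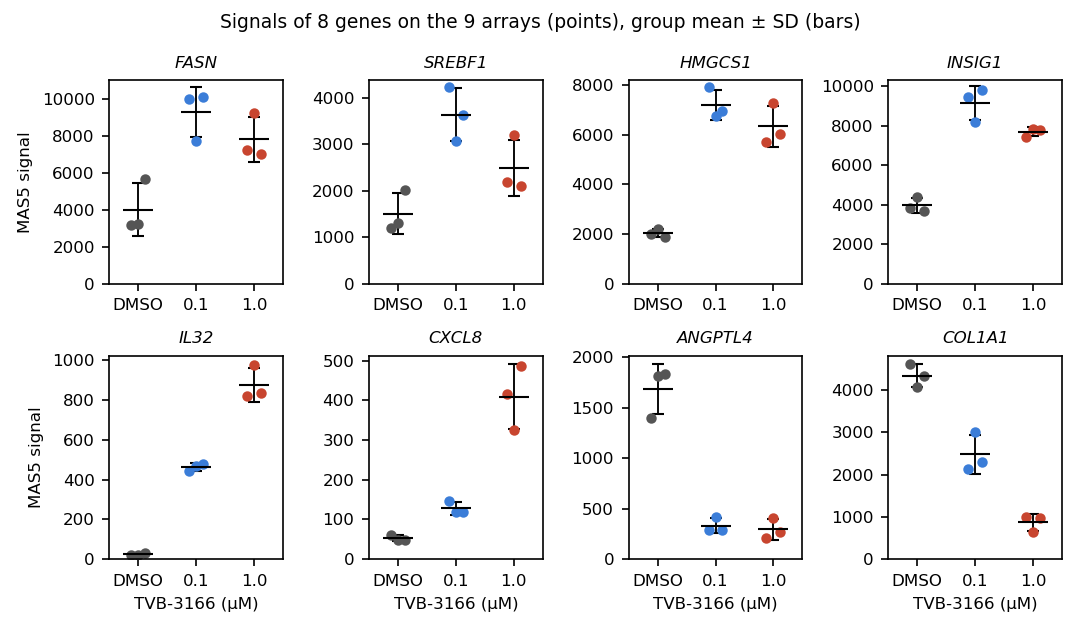
MAS5 signal (linear axis) of 8 genes in DMSO, 0.1 µM and 1.0 µM TVB-3166; points are arrays and bars are mean ± SD of 3 arrays. IL32 rose from 23.3 to 877 and ANGPTL4 fell from 1684 to 294 between DMSO and 1.0 µM.

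Genes that make fatty acids rose at 1.0 µM. FASN (Entrez gene 2194, chromosome 17, 82078338 to 82098236), whose product makes palmitate, rose by 1.01 ± 0.21 (adjusted p = 0.0039; signal 3999, SD 1420, to 7804, SD 1213). ME1, which supplies NADPH, rose by 2.21 ± 0.10, ACSS2, which makes acetyl-CoA from acetate, by 2.46 ± 0.17, and ELOVL6, an elongase of long chains, by 1.47 ± 0.17. SREBF1 (Entrez gene 6720), a transcription factor of lipid synthesis genes, rose by 0.73 ± 0.20 (adjusted p = 0.0214) and the desaturase SCD (Entrez gene 6319) by 0.62 ± 0.21 (adjusted p = 0.0491), the lowest of its 4 probe sets, which reach 1.64. In the list of fatty acid synthesis and desaturation 12 genes rose, 1 fell and 6 were not called (13 rose and 1 fell adjusted over the list alone); the faller was TECR (−0.45), a reductase of chain elongation. The list averaged 0.70 (adjusted p = 2.41e-05), and 0.67 in the lower and 0.78 in the higher spike set. The list had adjusted p = 0.0669 with an estimated correlation. For this probe set SCD lost its call without DMSO replicate 1 (adjusted p = 0.170), 2 (0.0848) or 3 (0.0755), 0.1 µM replicate 3 (0.0628), or 1.0 µM replicate 2 (0.138) or 3 (0.0872). It was also lost without the filter (0.0869), with median centring (0.0644), without the variance trend (0.0878), with robust eBayes (0.0544) and with the replicate block (0.0972). SREBF1 lost it without DMSO replicate 1 (0.0851) or 2 (0.0801) or 1.0 µM replicate 2 (0.0636) and without the variance trend (0.0565). In the lower spike set alone FASN (0.75, adjusted p = 0.0614) and SREBF1 (0.46, 0.181) were not called. In the higher set they were at 1.52 and 1.29, and in the lower and higher sets ACSS2 was at 2.26 and 2.86 and ELOVL6 at 1.67 and 1.06.

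Sterol genes rose as well. HMGCS1 (Entrez gene 3157), the HMG-CoA synthase gene, rose by 1.63 ± 0.11 (adjusted p = 1.55e-06), MVD by 1.68 ± 0.17, FDPS by 1.47 and HSD17B7 by 0.83, all enzymes of cholesterol synthesis. INSIG1 (Entrez gene 3638), which retains SREBP proteins in the endoplasmic reticulum, rose by 0.96 ± 0.10 (adjusted p = 4.18e-05). In the list of cholesterol synthesis and uptake 17 genes rose and 3 were not called (18 rose and 1 fell adjusted over the list alone), with a mean of 0.79 (adjusted p = 1.51e-11), 0.74 and 0.87 in the lower and higher spike sets. This list had adjusted p = 0.0967 with an estimated correlation. Targets of LXR, the sterol-sensing receptor, averaged 0.53 (0.53 and 0.52 within the spike sets; adjusted p = 0.000987, and adjusted p = 0.0456 with an estimated correlation): 6 rose, 1 fell and 3 were not called (8 rose and 1 fell adjusted over the list alone). Among them the sterol exporter ABCA1 rose by 1.76 ± 0.15, the ubiquitin ligase gene MYLIP by 1.14 and the acyltransferase gene LPCAT3 by 0.90, while PCDH18 fell by 2.08 ± 0.19 against the direction of the list.

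The amino acid stress response was among the strongest rises. Of the ATF4 and integrated stress response list 24 genes rose and 3 were not called (25 rose adjusted over the list alone), with a mean of 1.20 (adjusted p = 3.46e-20), 1.15 and 1.30 in the lower and higher spike sets. As a set these had adjusted p = 0.0593 with an estimated correlation. SLC7A11, the cystine transporter gene, rose by 2.42 ± 0.09, the pseudokinase gene TRIB3 by 2.02, the tryptophanyl-tRNA synthetase gene WARS1 by 1.99 ± 0.09, CHAC1, which degrades glutathione, by 1.81, the stress transcription factor DDIT3 by 1.66 and the arginine transporter SLC7A1 by 1.20 ± 0.08. The 3 probe sets of SLC7A11 spread from 1.55 to 2.802. NRF2 and oxidative stress genes averaged 0.77 (0.77 and 0.76 within the spike sets; adjusted p = 5.83e-07): 11 rose and 8 were not called, the same adjusted over the list alone, but adjusted p = 0.128 with an estimated correlation. OSGIN1 rose by 2.43, the haem oxygenase gene HMOX1 by 1.99, the sulfiredoxin gene SRXN1 by 1.61 ± 0.12 and GCLM, for glutathione synthesis, by 1.59 ± 0.12.

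Among interferon response genes 16 rose and 10 were not called (19 rose adjusted over the list alone), with a mean of 0.91 (0.91 and 0.89 within the spike sets; adjusted p = 9.93e-13). The exonuclease gene ISG20 rose by 2.35 ± 0.10, and the antiviral genes IFIT2, IFIT3 and OASL by 2.28 ± 0.10, 2.16 ± 0.12 and 1.73. NF-kB and inflammatory cytokine genes averaged 0.96 (0.98 and 0.90; adjusted p = 8.76e-09): 13 rose, 1 fell and 4 were not called (13 rose and 2 fell adjusted over the list alone). The chemokine genes CXCL8 and CCL5 rose by 2.63 ± 0.20 and 2.26 ± 0.14, the adhesion gene ICAM1 by 2.16 ± 0.15 and LIF by 1.35; the chemokine gene CXCL6 fell (−0.78) against the direction of the list. In the list of ERK pathway output 12 genes rose and 7 were not called (15 rose adjusted over the list alone), with a mean of 0.92 (0.91 and 0.94; adjusted p = 1.33e-09). MAFF, a small Maf factor, rose by 2.56 ± 0.12, the EGF-family ligand HBEGF by 2.23 ± 0.10, the phosphatase gene DUSP5 by 1.46 and ETV5 by 1.40. Rises depend on the probe set for HBEGF (0.53 to 2.23 over 3), ISG20 (2.35 to 3.98 over 2) and CXCL8 (1.80 to 2.63 over 2). With an estimated correlation the adjusted p of these 3 lists was 0.00537, 0.00633 and 0.00633.

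Cell cycle genes fell nearly as a whole. Of the mitosis and proliferation list 28 genes fell and only CENPA (−0.32, adjusted p = 0.058) was not called (29 fell adjusted over the list alone); the mean was −1.15 (−1.13 and −1.19 in the lower and higher spike sets; adjusted p = 6.04e-26, and 0.00925 with an estimated correlation). The checkpoint kinase gene BUB1B fell by 1.72 ± 0.11, CDK1 by 1.48 ± 0.12, the kinetochore gene CENPF by 1.31 ± 0.09 and the proliferation marker MKI67 by 1.05. DNA replication and S phase genes averaged −0.91 (−0.90 and −0.94; adjusted p = 6.97e-19, and 0.00836 with an estimated correlation): 26 fell and 5 were not called (29 fell adjusted over the list alone). RRM2, of ribonucleotide reductase, fell by 1.92 ± 0.10, the replication factors MCM10 and GINS1 by 1.55 and 1.41, and TYMS and TK1, which make thymidine nucleotides, by 1.29 and 1.23. The 3 probe sets of MCM10 spread from −1.83 to −0.76.

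Hypoxia and glycolysis genes fell by a mean of −0.49 (−0.50 and −0.47 within the spike sets; adjusted p = 1.68e-06), with 12 falls, 1 rise and 12 not called (1 rose and 13 fell adjusted over the list alone). Together they had adjusted p = 0.0967 with an estimated correlation. NDRG1, a stress-regulated gene, fell by 1.93 ± 0.17, ANKRD37 by 1.53 ± 0.12, the prolyl hydroxylase gene P4HA1 by 0.94 ± 0.09 and the histone demethylase gene KDM3A by 0.68, while the hexokinase gene HK1 rose by 0.36 against the list. In autophagy and lysosome genes 9 rose, 1 fell and 13 were not called, the same 9 and 1 adjusted over the list alone, with a mean of 0.28 (0.26 and 0.33; adjusted p = 0.00652). These genes had adjusted p = 0.23 with an estimated correlation. The sterol transporter NPC1 rose by 1.14 ± 0.13, the autophagy receptor SQSTM1 by 0.99, ATG7 by 0.77 and MAP1LC3B by 0.69, and the protease gene CTSB fell (−0.39). The 4 probe sets of ATG7 spread from −0.02 to 0.93, the 5 of SQSTM1 from 0.59 to 2.18 and the 3 of NPC1 from 0.39 to 1.14. These rises thus depend on the probe set. MYC (Entrez gene 4609) rose by 0.49 ± 0.11 (adjusted p = 0.00812) and CTNNB1 (Entrez gene 1499), which encodes beta-catenin, fell by 0.43 ± 0.10 (adjusted p = 0.00741). The 3 probe sets of CTNNB1 spread from −0.54 to −0.13.

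**Figure D2:**
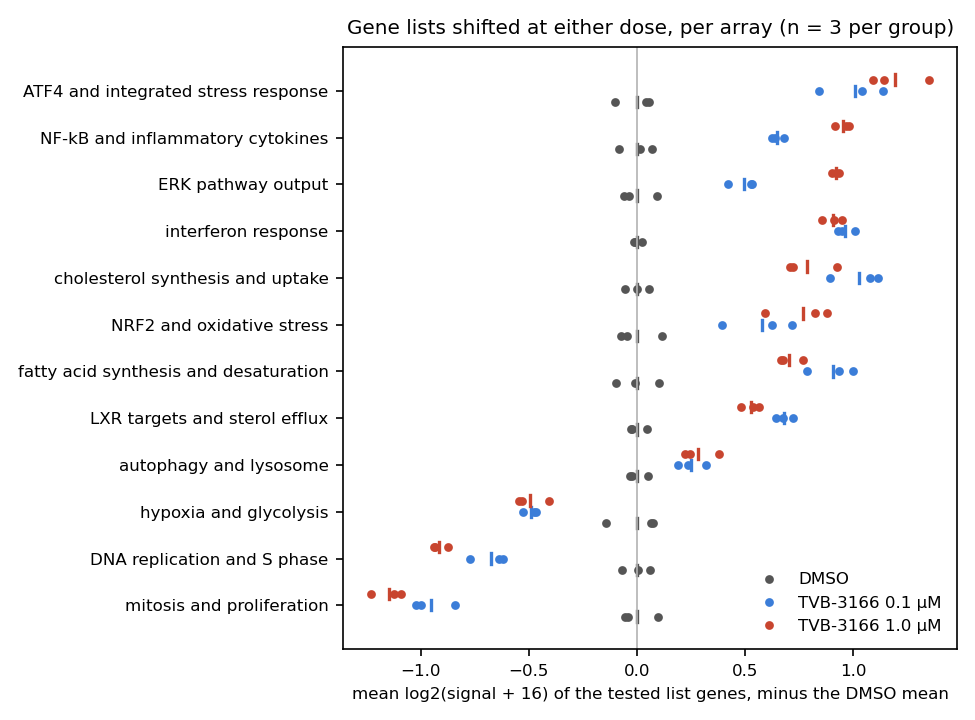
Mean log2(signal + 16) of the tested genes of 12 lists minus the DMSO mean; points are arrays (grey DMSO, blue 0.1 µM, red 1.0 µM, 3 each) and ticks are group means. Mitosis genes lay lowest (−1.15 at 1.0 µM) and ATF4 genes highest (1.20).

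Other lists of lipid handling were not called by camera at 1.0 µM, with genes moving both ways. The fry test did call triglyceride and lipid droplet genes up (adjusted p = 0.0167) and fatty acid oxidation genes down (0.000994). Triglyceride and lipid droplet genes had 4 rises and 3 falls of 18 (7 and 3 adjusted over the list alone; mean 0.17, adjusted p = 0.405), among them the phosphatidate phosphatase gene LPIN1 (1.55 ± 0.09) and the acyltransferase gene AGPAT2 (−1.20 ± 0.09). Fatty acid uptake and binding had 2 rises, with the lipoprotein receptor VLDLR at 0.87, and 1 fall (3 and 1 adjusted over the list alone; 0.12, adjusted p = 0.614). Fatty acid oxidation had 2 rises and 6 falls of 22 (2 and 7 adjusted over the list alone). Its mean was −0.24 and its median −0.13 (camera adjusted p = 0.0691). The falls included ANGPTL4 (−2.50), PDK4 (−1.29) and CPT1A (−0.63), so the mean leans on ANGPTL4. Phospholipid and sphingolipid synthesis had 3 rises and 4 falls of 31 (3 and 5 adjusted over the list alone; −0.05, adjusted p = 0.614), with PCYT2 at 1.13 ± 0.11. Protein palmitoylation had 2 rises (ZDHHC14 0.70, ZDHHC18 0.46) and 1 fall (ZDHHC20 −0.90) of 19, the same adjusted over the list alone (−0.04, adjusted p = 0.811).

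Signalling and state lists were not called by camera either. By fry, however, Wnt and beta-catenin targets (adjusted p = 0.000124) and mesenchymal state and matrix genes (0.0006) were called down. It also called apoptosis regulators up (6.28e-05). Wnt and beta-catenin targets had 2 rises, with FOSL1 at 1.63, and 3 falls, with FZD7 at −0.56 (2 and 5 adjusted over the list alone; mean −0.05, adjusted p = 0.405). MYC targets and ribosome biogenesis had 4 falls of 25, EIF4E (−0.46), LDHA (−0.57), NOP58 (−0.27) and TFRC (−0.34), of which 1 stayed adjusted over the list alone (−0.07, adjusted p = 0.403). FOXO targets had 8 rises and 3 falls (9 and 3 adjusted over the list alone; 0.17, adjusted p = 0.168), with SOD2 at 1.48 and CITED2 at −0.74. For p53 target genes these were 4 and 3, the same adjusted over the list alone (0.07, adjusted p = 0.743). Apoptosis regulators had 10 rises and 4 falls of 26 (11 and 5 adjusted over the list alone; 0.23, adjusted p = 0.0722). ER chaperone and ER-associated degradation genes had 7 rises and 7 falls of 25 (8 and 8 adjusted over the list alone; 0.00, adjusted p = 0.696). Epithelial state genes had 4 and 4 of 22 (5 and 4 adjusted over the list alone; 0.00, adjusted p = 0.850), and mesenchymal state and matrix genes 3 rises and 5 falls of 25, the same adjusted over the list alone (−0.29, adjusted p = 0.0691).

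Few marker genes of other cell types were called. Blood and immune markers had 0 called of 7 tested (list adjusted p = 0.743 by camera). Hepatocyte and prostate markers had 1 fall of 6, that of the protease gene TMPRSS2 (−1.39). That list had adjusted p = 0.614 by camera, while fry called it down (0.034). EGFL7 fell (−0.53, adjusted p = 0.0215) among the 2 endothelial markers tested, and of the pancreas acinar and endocrine markers 1 was tested and 0 called.

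At 1.0 µM against DMSO limma called 3240 of 13948 genes, 1711 higher and 1529 lower, of which 368 and 257 changed at least 2-fold. At unadjusted p under 0.05 there were 4840 genes, with 697 expected by chance, and in 37.2% of genes the groups did not overlap (10% by chance). The lower spike set alone (2 arrays per group) called 2652 genes. The higher set holds 1 array of each of these groups, so its count of 2925 takes its spread from the 0.1 µM arrays alone.

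At 0.1 µM against DMSO, SLCO4C1 rose by 3.88 ± 0.27 (signal 84.9 to 1480), IL32 by 3.63 ± 0.16, ACSS2 by 2.96 ± 0.17 (817 to 6366), KLHDC7B by 2.75, the interleukin 21 receptor gene IL21R by 2.70 ± 0.24 (from a DMSO signal of 17.0), IFIT2 by 2.56 ± 0.10 and CCL5 by 2.40 ± 0.14. AKAP14, an anchoring protein of protein kinase A, rose by 2.87 ± 0.28 from a DMSO signal of 3.67, at the noise floor. The size of the rise depends on the probe set for SLCO4C1 (1.21 to 3.88 over 2), KLHDC7B (1.46 to 2.75 over 2) and IL21R (0.47 to 2.70 over 2). It does so too for AKAP14 (2.08 to 2.87 over 2) and IFIT2 (1.87 to 2.56 over 2), as does the fall of FAM13A (−1.67 to −0.99 over 3). ART5 at 0.1 µM has some arrays and TBXT a mean signal (18.7) below the filter level, so their falls are understated. ANGPTL4 fell by 2.30 ± 0.22 (1684 to 331), ART5 by 2.20 ± 0.42, the mucin gene MUC16 by 1.93 ± 0.40, NDRG1 by 1.79 ± 0.17, TBXT (brachyury) by 1.76 ± 0.40, CDH10 by 1.63 ± 0.23, FAM13A by 1.62 ± 0.17 and MEGF6 by 1.59 ± 0.18. In the lower spike set alone the calls of ART5 (−1.21, adjusted p = 0.1098), MUC16 (−1.93, 0.155), TBXT (−1.64, 0.130) and CDH10 (−1.51, 0.0769) ended, and in the higher set that of TBXT (−1.98, 0.0716). Values in the lower and higher sets differed for ANGPTL4 (−1.896 and −2.596), FAM13A (−1.19 and −1.82), IL21R (2.33 and 3.098) and ART5, which was at −2.81 in the higher set.

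Lipid synthesis genes rose at 0.1 µM. FASN rose by 1.25 ± 0.21 (adjusted p = 0.00181; signal 3999 to 9265), SREBF1 by 1.29 ± 0.20 (adjusted p = 0.00138) and SCD by 0.73 ± 0.21 (adjusted p = 0.0394), the lowest of its 4 probe sets, which reach 1.81. The fatty acid synthesis and desaturation list averaged 0.91 (0.78 and 0.98 in the lower and higher spike sets; adjusted p = 8.7e-11, and 0.012 with an estimated correlation): 13 rose and 6 were not called (14 rose adjusted over the list alone), with ME1 at 2.07 and ELOVL6 at 1.53. Cholesterol synthesis and uptake averaged 1.03 (0.92 and 1.04; adjusted p = 6.46e-23, and 0.0273 with an estimated correlation): 16 rose and 4 were not called (19 rose adjusted over the list alone), with HMGCS1 at 1.82, MVD at 2.16, FDPS at 1.84 and INSIG1 at 1.20. Among LXR targets 6 rose, 1 (PCDH18, −1.04) fell and 3 were not called (8 and 1 adjusted over the list alone); the mean was 0.68 (0.67 and 0.65; adjusted p = 3.61e-06, and 0.0107 with an estimated correlation), with ABCA1 at 1.65 and LPCAT3 at 1.44. The 2 probe sets of LPCAT3 disagreed (−0.27 to 1.44). On this probe set SCD lost its call without DMSO replicate 1 (0.149), 2 (0.0747) or 3 (0.0694), 0.1 µM replicate 1 (0.143) or 3 (0.163) or 1.0 µM replicate 3 (0.0572). It was also lost without the filter (0.0730), without the variance trend (0.0804) and with the replicate block (0.0898). In the lower spike set alone FASN (0.87, adjusted p = 0.190), SREBF1 (0.97, 0.122) and SCD (0.34, 0.340) were not called, and in the higher set FASN was at 1.64 and SREBF1 at 1.58.

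Stress and immune genes also rose at 0.1 µM. ATF4 and integrated stress response genes averaged 1.01 (0.87 and 1.03 within the spike sets; adjusted p = 4.13e-25, and 0.0285 with an estimated correlation): 23 rose and 4 were not called (25 rose adjusted over the list alone), with SLC7A11 at 2.02 and TRIB3 at 1.84. In the interferon response 18 rose and 8 were not called (19 rose adjusted over the list alone; mean 0.96, within the spike sets 0.94 and 0.96; adjusted p = 2.7e-20, and 0.00135 with an estimated correlation), with IFIT3 at 2.22 and OASL at 2.15. NF-kB and inflammatory cytokine genes averaged 0.65 (0.65 and 0.63; adjusted p = 1.17e-08, and 0.00903 with an estimated correlation): 12 rose and 6 were not called (13 rose adjusted over the list alone), with ICAM1 at 1.69 and CXCL8 at 1.08. ERK pathway output had 9 rises and 10 not called, also 9 adjusted over the list alone (0.49, within the spike sets 0.51 and 0.51; adjusted p = 4.28e-07, and 0.00989 with an estimated correlation), with HBEGF at 1.48 (0.13 to 1.48 over 3 probe sets) and MAFF at 1.47. NRF2 and oxidative stress genes averaged 0.58 (0.45 and 0.55; adjusted p = 1.07e-07), with 8 rises and 11 not called (10 rises adjusted over the list alone) and HMOX1 at 1.38. The list had adjusted p = 0.12 with an estimated correlation. Autophagy and lysosome genes had 6 rises, NEU1 (0.74) and MAP1LC3B (0.53) among them (NEU1 not called in the lower spike set alone, adjusted p = 0.0722), and 17 not called (8 rises adjusted over the list alone; mean 0.25, 0.22 in each spike set, adjusted p = 0.00234). This list had adjusted p = 0.209 with an estimated correlation.

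Cell cycle and hypoxia genes fell at 0.1 µM. Of mitosis and proliferation genes 27 fell and 2 were not called, also 27 adjusted over the list alone (mean −0.95, −0.86 and −0.97 in the lower and higher spike sets; adjusted p = 4.31e-30, and 0.00903 with an estimated correlation), with BUB1B at −1.38 and CDK1 at −1.17. Among DNA replication and S phase genes 23 fell and 8 were not called (24 fell adjusted over the list alone; −0.68, within the spike sets −0.62 and −0.71; adjusted p = 1.42e-18, and 0.00903 with an estimated correlation), with RRM2 at −1.33 and MCM10 at −1.37. Hypoxia and glycolysis genes had 10 falls and 15 not called (13 falls adjusted over the list alone; −0.49, within the spike sets −0.49 and −0.54; adjusted p = 1.78e-08), with ANKRD37 at −1.49 and KDM3A at −0.81 (KDM3A −0.62, adjusted p = 0.0722 in the lower spike set alone). As a set these had adjusted p = 0.0534 with an estimated correlation. CTNNB1 fell by 0.36 (adjusted p = 0.0334), a call lost without DMSO replicate 1 (0.0987) or 3 (0.0981), 0.1 µM replicate 1 (0.124) or 3 (0.144) or 1.0 µM replicate 3 (0.0551), without the variance trend (0.0692), with the replicate block (0.0942) and within the lower (0.226) or higher (0.0549) spike set. MYC was at 0.19 (adjusted p = 0.338).

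The remaining lists were not called by camera at 0.1 µM with all arrays pooled. By fry, Wnt targets (adjusted p = 0.000366), mesenchymal genes (0.00999) and fatty acid oxidation genes (0.0258) were called down. It called apoptosis regulators up (0.00189). The fatty acid oxidation list holds ANGPTL4 (−2.30). Rises and falls were 3 and 3 for triglyceride and lipid droplet genes (4 and 3 adjusted over the list alone; adjusted p = 0.621), with LPIN1 at 1.61, 2 and 0 for fatty acid uptake (3 and 0; 0.727), 2 and 4 for fatty acid oxidation (2 and 5; 0.283), with PDK4 at −0.79, 2 and 1 for phospholipid synthesis (2 and 1; 0.870), with PCYT2 at 1.36, and 0 and 0 for palmitoylation (0 and 0; 0.841). They were 4 and 7 for ER chaperones (6 and 9 adjusted over the list alone; adjusted p = 0.509), with XBP1 at 1.06 and CALR at −0.67, 5 and 3 for apoptosis regulators (6 and 4; 0.221), with PMAIP1 at 1.08, 2 and 1 for p53 targets (2 and 1; 0.841), and 1 and 2 for Wnt targets (1 and 2; 0.302). MYC targets and ribosome biogenesis had 0 and 3 (0 and 3 adjusted over the list alone; mean −0.06, adjusted p = 0.283), but with the spike set as a block this list was called (−0.12, adjusted p = 0.0105). FOXO targets had 5 and 2 (6 and 3 adjusted over the list alone; adjusted p = 0.365), with TXNIP at 1.13, epithelial genes 4 and 1 (4 and 1; 0.870), with CLDN1 at 1.22, and mesenchymal genes 4 and 5 (4 and 5; 0.179), with SPARC at −1.12. Blood and immune markers had 0 called (adjusted p = 0.841), and of hepatocyte and prostate markers TMPRSS2 fell (−0.64; list adjusted p = 0.418).

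At 0.1 µM limma called 1674 genes, 961 higher and 713 lower, with 220 and 87 at least 2-fold, 3544 at unadjusted p under 0.05 and non-overlapping groups in 30.03% of genes (10% by chance). The count was 1092 without DMSO replicate 1, 1054 without 0.1 µM replicate 1, 843 without 0.1 µM replicate 3, 324 in the lower and 1897 in the higher spike set.

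Most genes called at 0.1 µM were also called at 1.0 µM. IL32, SLCO4C1, SLC7A11 and HMGCS1 are among 859 genes called higher at both, and ANGPTL4, NDRG1, BUB1B and RRM2 among 636 called lower at both, where independent calls would share 117.9 and 78.2. Of the 1674 genes called at 0.1 µM these 1495 make 89.3%, while 3240 genes were called at 1.0 µM and 3418 at either dose. In 1 gene, CRYAA, a lens crystallin, the calls were opposite. Simulated unchanged groups with shared DMSO arrays gave 0 shared calls, as hardly any gene is called without an effect, so the part of the overlap that comes from the shared arrays is not known. Across genes the fold changes at both doses correlated at 0.833, against 0.50 ± 0.01 in the simulations (the genes are not independent replicates). Their covariance was 0.153 against 0.021 simulated, a difference of 0.132, and 80.1% of genes had the same sign against 66.7%. Of the shared calls 1176 (78.7%) were larger at 1.0 µM, and without 0.1 µM replicate 3 the shared calls were 799 and in the lower spike set alone 321.

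**Figure D3:**
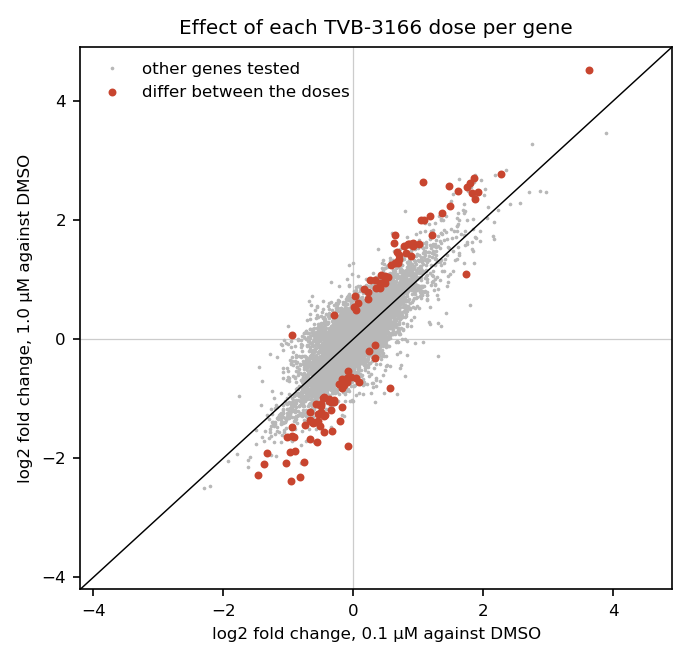
Log2 fold change of each tested gene at 0.1 µM (x) and 1.0 µM (y) against DMSO; points are genes, red marks the 114 that differed between doses, and the diagonal marks equal effects. Fold changes correlated at 0.833 across genes.

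Between 1.0 and 0.1 µM the largest rise, on the probe set standing for each gene, was in the chemokine gene CXCL8 (Entrez gene 3576, chromosome 4, 73740569 to 73743716). It was 1.55 ± 0.20 (adjusted p = 0.00541), with mean signals of 52.4 in DMSO, 128 at 0.1 µM and 409.9 at 1.0 µM. Against DMSO its 2 probe sets gave 0.87 and 1.08 at 0.1 µM and 1.80 and 2.63 at 1.0 µM. Its size and rank thus depend on the probe set. MAFF was higher by 1.10 ± 0.12 (adjusted p = 0.00227; 422, 1188 and 2562), CAMTA2, a transcription activator, by 1.09 ± 0.20 (0.0288) and SRXN1 by 0.99 ± 0.12 (0.0032). HK2 (Entrez gene 3099), a hexokinase gene, was higher by 1.01 ± 0.20 (0.0447), with mean signals of 271 in DMSO, 131 at 0.1 µM and 278 at 1.0 µM. Its 3 probe sets gave values at 0.1 µM from −0.94 to 0.87. Lower at 1.0 µM were TICRR (Entrez gene 90381, chromosome 15, 89575469 to 89628023), a replication initiation gene, at −1.71 ± 0.30 (0.0249; signal 30.2 at 1.0 µM, below the filter level), COL1A1 at −1.50 ± 0.16 (0.00229), CDH3 at −1.43 ± 0.19 (0.00556) and CRABP2, a retinoic acid binding protein, at −1.30 ± 0.12 (0.00227; 12869, 7589 and 3088). CRYAA, at −1.38 ± 0.15 (0.00227), rose at 0.1 µM (0.56) and fell at 1.0 µM (−0.82).

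Of the lists, ERK pathway output was 0.42 higher at 1.0 than at 0.1 µM (0.40 and 0.42 in the lower and higher spike sets; adjusted p = 1.25e-09, and 0.015 with an estimated correlation), with 3 genes called, HBEGF (0.74) and DUSP5 (0.79) among them (10 adjusted over the list alone). NF-kB and inflammatory cytokine genes were 0.31 higher (0.33 and 0.27; adjusted p = 4.26e-05, and 0.0391 with an estimated correlation), with CXCL8 called (6 adjusted over the list alone). ATF4 and integrated stress response genes were 0.19 higher (0.27 and 0.26; adjusted p = 0.000217) with 0 called (6 adjusted over the list alone). Together they had adjusted p = 0.438 with an estimated correlation, and the call ended without 0.1 µM replicate 2 (0.11, 0.140) or 1.0 µM replicate 2 (0.11, 0.181). Each of these arrays is the only one of its dose in its spike set. With the spike set as a block the list was at 0.25 (camera at the preset correlation, adjusted p = 4.36e-09). NRF2 and oxidative stress genes were 0.19 higher (0.32 and 0.21; adjusted p = 0.0018) with GCLC (0.73), GCLM (0.70) and SRXN1 called (6 adjusted over the list alone). These genes had adjusted p = 0.415 with an estimated correlation, and the call ended without 0.1 µM replicate 2 (0.10, 0.206) or 1.0 µM replicate 2 (0.13, 0.188). With the spike set as a block they were at 0.26 (camera at the preset correlation, adjusted p = 1.3e-07).

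Cell cycle and lipid synthesis lists were lower at 1.0 than at 0.1 µM. DNA replication and S phase genes were lower by 0.24 (−0.28 and −0.23 in the lower and higher spike sets; adjusted p = 2.12e-08), with RRM2 (−0.59) and TK1 (−0.56) called (3 adjusted over the list alone). The list had adjusted p = 0.0823 with an estimated correlation. Mitosis and proliferation genes were lower by 0.19 (−0.27 and −0.22; adjusted p = 1.55e-06), with 0 called and 0 adjusted over the list alone. This list had adjusted p = 0.232 with an estimated correlation. Cholesterol synthesis and uptake genes were lower by 0.24 (−0.18 and −0.17; adjusted p = 1.61e-07), with TM7SF2 (−0.66), a sterol reductase gene, called (3 adjusted over the list alone). As a set these had adjusted p = 0.258 with an estimated correlation. Fatty acid synthesis and desaturation genes were lower by 0.20 (−0.12 and −0.20; adjusted p = 0.00865) with 0 called and 0 adjusted over the list alone. Together they had adjusted p = 0.258 with an estimated correlation, and the call ended without 0.1 µM replicate 3 (−0.16, 0.0906). With the spike set as a block the list was not called (−0.17, adjusted p = 0.0570).

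Between doses limma called 114 genes, 54 higher and 60 lower at 1.0 µM, 4 and 10 of them at least 2-fold; 1726 had an unadjusted p under 0.05, and groups did not overlap in 18.5% of genes (10% by chance). The number was unstable: 17, 36 and 56 without 0.1 µM replicate 1, 2 or 3, 26, 186 and 11 without 1.0 µM replicate 1, 2 or 3, 1 in the lower and 304 in the higher spike set. Leaving out 0.1 µM replicate 1 or 1.0 µM replicate 1 or 3 ended the calls of HK2, TICRR, CAMTA2, TK1, RRM2, TM7SF2, GCLC, GCLM and DUSP5 (adjusted p 0.0813 to 0.215), and 1.0 µM replicate 3 also those of CXCL8 (0.0535) and HBEGF (0.0552). Without 0.1 µM replicate 2 the values were 0.0843 for HK2, 0.0957 for TICRR, 0.0726 for CAMTA2, 0.0817 for TK1, 0.0783 for RRM2, 0.0758 for DUSP5 and 0.0519 for GCLM. Without 0.1 µM replicate 3 they were 0.111 for HK2, 0.0625 for CAMTA2, 0.0958 for TK1, 0.0917 for TM7SF2, 0.0738 for GCLC and 0.0567 for GCLM, and HK2 was also lost without DMSO replicate 2 (0.0619) or 1.0 µM replicate 2 (0.0716). With the mean of a gene's probe sets the calls of HK2 (0.52, 0.233), TICRR (−1.21, 0.171), HBEGF (0.62, 0.0992), TK1 (−0.41, 0.116), RRM2 (−0.52, 0.0534) and GCLM (0.68, 0.0573) also ended.

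Other settings ended calls between doses too. Without the variance trend CAMTA2 (0.0929), HK2 (0.0910), TICRR (0.0613), DUSP5 (0.0835), RRM2 (0.0831), TK1 (0.0831), TM7SF2 (0.0852), GCLC (0.0831) and GCLM (0.0835) were lost. The replicate block ended all of these calls but that of CAMTA2 (adjusted p 0.0584 to 0.0926). Without the filter CAMTA2 (0.0509), HK2 (0.0877) and TICRR (0.0508) were lost, and with only the 6 arrays compared TICRR (0.0622), RRM2 (0.0532), TK1 (0.0596) and TM7SF2 (0.0552). In the lower and higher spike sets TICRR was at −2.21 and −1.02 and CXCL8 at 1.79 and 1.21. Of the dose-difference genes 10 were called higher and 23 lower at 1.0 µM only.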

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

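The tests of the sterol and interferon patterns in the next paragraphs were chosen only after those results were seen, while the regroupings of the arrays were planned before their values were known.

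At 1.0 µM the cholesterol synthesis and uptake genes were higher than in DMSO but lower than at 0.1 µM, by −0.24 (fatty acid synthesis genes by −0.20, a call that ended with the spike set as a block, −0.17, adjusted p = 0.0570, and without 0.1 µM replicate 3, 0.0906; adjusted p = 0.258 with an estimated correlation). An uneven spread of the spike sets over the doses could lower sterol genes. As the whole cause it needed a value above −0.1 with the spike set as a block. The difference was then −0.187 ± 0.034 (standard error across genes, which are not independent), against −0.242 without the block. This speaks against it as the whole cause, while it may make a part. Array scaling could also lower sterol genes: after quantile normalization the difference was −0.216 ± 0.039, which speaks against it. What also remains open is variation shared by these genes between arrays, since adjusted p = 0.258 with an estimated correlation. A compound effect that is smaller on sterol genes at the higher dose may be the cause, and arrays from more separate cultures would be needed to settle it.

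Interferon response genes rose at both doses in a culture of 1 cell line. RNA of blood cells could carry such genes, but 16 blood and immune markers averaged 0.0486 ± 0.0507 at 1.0 µM, which speaks against a large amount of it. Only 7 of these markers lie above the filter, and their median DMSO signal over all 16 was 32.7. Markers this dim could miss a small amount. By the split used, DMSO and 1.0 µM hold equal numbers of each spike set, so only the 0.1 µM comparison can test their uneven spread. At 0.1 µM the list averaged 0.962, and 0.952 ± 0.143 with the spike set as a block. This speaks against uneven spike sets as its cause at 0.1 µM. Transcription of interferon ligands stays open: the smallest adjusted p among 6 ligand probe sets was 0.305, but the highest upper bound of a rise was 1.29.

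Calling genes by limma after regrouping the arrays gave the following. For 1.0 µM against DMSO the real grouping of the 6 arrays called 2789 genes and was 1 of 10 splits with as many, where the highest other called 0. For 0.1 µM it called 1593, again 1 of 10 with a highest other of 0, and 10 splits are too few for a share under 0.05. Between doses the real grouping called 65 genes and 2 of 10 splits called as many; the other, with 1254, parts the 3 arrays of the higher from the 3 of the lower spike set, so the samples hold a structure larger than the dose difference. With the spike set as a block 256 genes differed between doses. An F test over the 3 groups called 2634 genes, and of 100 splits only the real grouping reached this (highest other 1741). A random regrouping of these arrays would thus seldom call as many. This cannot exclude a chance difference between cultures, as the replicates may not be separate cultures. The spike sets also make the arrays unequal.

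Other lists differed between the doses, 1.0 minus 0.1 µM: ERK pathway output 0.42, NF-kB and inflammatory cytokines 0.31, ATF4 and integrated stress response 0.19, NRF2 and oxidative stress 0.19, mitosis and proliferation −0.19, and DNA replication and S phase −0.24. The calls of ATF4 (adjusted p = 0.438 with an estimated correlation), NRF2 (0.415), mitosis (0.232) and DNA replication (0.0823) rest on the preset correlation, and those of ATF4 and NRF2 also end with 1 array left out. With the spike set as a block ATF4 genes were at 0.25 and NRF2 genes at 0.26. Both stayed called by camera at the preset correlation (adjusted p = 4.36e-09 and 1.3e-07). Single genes differed by 1.55 (CXCL8), 1.10 (MAFF), 1.09 (CAMTA2), 1.01 (HK2), 0.99 (SRXN1), −1.71 (TICRR), −1.50 (COL1A1), −1.43 (CDH3), −1.38 (CRYAA) and −1.30 (CRABP2).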

How the results depend on the processing

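The 4 settings built on the spike sets were chosen only after the data were seen; all others were planned. The starting values are 3240 genes at 1.0 µM, 1674 at 0.1 µM, 1495 at both, 114 between doses, and 12, 12 and 8 lists.

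The count between doses moved most: 67 without the filter, 23 without the variance trend, 65 from the 6 arrays alone, 1953 with array weights, 256 with the spike set as a block, 318 with that block after quantile normalization, 1 in the lower and 304 in the higher spike set. The single spike sets have 2 (lower) and 1 (higher) residual degrees of freedom and compare some groups of 1 array. The cause of these moves was not tested.

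Testing all 32768 probe sets above the filter gave 5772 at 1.0 µM, 2703 at 0.1 µM, 2399 at both and 92 between doses. These are counts of probe sets, with several for many genes, and cannot be set against counts of 13948 genes. A fold of at least 1.5 as well left 1788 and 924 genes by its construction. In the lower spike set alone 324 genes were called at 0.1 µM and 321 at both. For lists, an estimated correlation left 6 at 1.0 µM and 2 between doses, and the higher spike set alone gave 13 lists between doses; the cause of either was not tested. The fry test called 18, 16 and 6 lists. Between doses it called 3 of the 8, ERK pathway output, NF-kB and DNA replication. It did not call cholesterol (adjusted p = 0.0613), mitosis (0.0613), fatty acid synthesis (0.124), NRF2 (0.174) or ATF4 (0.236). Lists that camera did not call there but fry did were apoptosis regulators (up, 0.018), LXR targets (down, 0.0422) and mesenchymal genes (down, 0.0422).

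Same-number replicates were not alike after group means were removed (r −0.34 to 0.22 over 9 pairs). Most of these pairs cross the spike sets, and pairs across sets averaged −0.10 against 0.11 within a set. Those within a set gave 0.22, 0.04 and −0.08, so the check cannot tell whether the numbers pair samples. The replicate block gave 2550, 1137 and 23 genes, 1035 at both doses, and 13, 12 and 8 lists.

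Leaving out 1 array at a time gave 2343 to 3329 genes at 1.0 µM, 843 to 2003 at 0.1 µM, 11 to 186 between doses and 799 to 1589 at both. Lists ranged from 12 to 14, 12 to 12 and 6 to 10.

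In 1 setting a list changed sign with a call in either fit: MYC targets and ribosome biogenesis between doses. It was at 0.0986 in the higher spike set alone against −0.00796 from all arrays (not called), and the cause was not tested. Sign changes without a call in either fit also occurred and were not counted. An example is this list at 1.0 µM against DMSO (−0.07 pooled, 0.05 in the higher set). Sizes were not compared. Otherwise, of 1290 list values 1260 kept their call or lack of one, 4 lost a call and 25 gained one. Of 2005 values of named genes 1927 kept theirs and 78 lost a call. Most named genes were chosen for their calls on these arrays (125 of 126 values called). With 1 array left out, 715 of 729 list values and 1070 of 1134 gene values kept their call or lack of one. The spike block added a call of apoptosis regulators between doses (0.11, adjusted p = 0.0309) and of MYC targets and ribosome biogenesis at 0.1 µM (−0.12, 0.0105), and ended that of fatty acid synthesis and desaturation between doses (−0.17, 0.0570). Array weights ended the calls of ATF4 (0.09, 0.322) and NRF2 (0.16, 0.207) between doses.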

Other observations

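The genes and families in this part were picked only after their values were seen; the tests of the complex I pattern were written before their values were known.

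Within several lists that were not called by camera, members moved both ways. Among apoptosis regulators the BCL2 relative BCL2A1 rose at 1.0 µM by 2.31 ± 0.19, the BH3-only gene PMAIP1 by 1.53 ± 0.11 and the death receptor TNFRSF10B by 1.29 ± 0.11, while the BH3-only gene BCL2L11 fell by 1.08 ± 0.09 (n = 3 arrays per group). At 0.1 µM PMAIP1, TNFRSF10B and BCL2L11 were at 1.08, 0.88 and −0.93. Of the ER genes, XBP1 rose by 1.33 ± 0.11 and HERPUD1 by 0.68, while the chaperone genes CALR, CRELD2 and PDIA4 fell by 0.91 ± 0.09, 0.85 and 0.64, a split within 1 list next to the rise of ATF4 genes. Among cell state genes the junction gene CLDN1 rose by 1.83 and the keratin gene KRT7 by 1.06, while KRT19 fell by 0.90 and ELF3 by 1.08. The matrix genes COL3A1 and SPARC fell by 1.51 and 1.36, and LOX rose by 1.06. LPCAT2, a phospholipid acyltransferase gene, fell by 1.22 ± 0.10 at 1.0 µM and by 0.50 at 0.1 µM, a difference of −0.72 (adjusted p = 0.00872).

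TMPRSS2 had mean signals of 1171, 748 and 437 in DMSO, 0.1 µM and 1.0 µM, so it fell by dose (−0.64 and −1.39; between doses −0.76, adjusted p = 0.00834). Among 175 families of genes with a shared name stem, the MCM family fell at both doses (−0.61 at 1.0 µM, 1 rose and 7 fell of 11; −0.48 at 0.1 µM; adjusted p = 0.002 and 0.00115), KIF genes were lower at 0.1 µM (−0.27, 3 rose and 11 fell of 34), and COL (−0.23, 27 genes) and NDUFA (−0.20, 12 genes) were lower at 1.0 than at 0.1 µM (adjusted p = 0.0474). None held with an estimated correlation (adjusted p 0.565 to 0.923).

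The NDUFA family led to 1 hypothesis, that respiratory complex I genes are lower at 1.0 than at 0.1 µM. Over 24 NDUFA and NDUFB genes, which include the NDUFA genes that prompted it, the difference was −0.188. Uneven spike sets could make part of it: with the spike set as a block it was −0.108 ± 0.029 (standard error across genes), which leaves this open. A fall shared by the respiratory chain needed a mean at or below −0.1 in its other genes. The 41 COX, UQCR, ATP5 and SDH genes averaged −0.131 ± 0.017. With the block they averaged −0.0446, which misses that limit, so a shared fall stays open. The shift may thus in large part go with the spike sets. A repeat of both doses on arrays hybridised together would be needed to settle it.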
